A study of Homo sapiens with 4 samples.

How the data were processed

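RNA was measured in 4 libraries of HT1080 fibrosarcoma cells with a KDAC8 (HDAC8) knockout. Per the labels' protocols, frozen cell pellets were used for total RNA, ribosomal RNA was removed with a Ribo-Zero Plus kit, and libraries were sequenced as read pairs. Per the submitters' processing notes, the tools were Trimmomatic 0.39, Bowtie2 2.5.4, RSEM 1.3.3 and DESeq2 1.46.0 with the GRCh38 build. The role of each tool, the gene annotation release, the strand setting and any filter are not given in the sources used here. The authors deposited a table of expected counts per Ensembl gene, one column per library, not scaled between libraries. That unit was read from the values, which are not negative, are not whole in 10.6% to 11.9% of cells and sum to different totals. An expected count can share a read among genes of similar sequence, so paralogs, pseudogenes and overlapping rows are uncertain.

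The table holds 60675 gene rows. Every per-sample column matched a sample by name, and 0 columns of per-sample values were left unused. Of the rows, 30772 were at 0 in every library, and 2116 shared their gene name with another row. Gene positions, classes, exonic lengths and GC content came from GENCODE release 29 (GRCh38), in which 94.03% of the gene IDs were found. The unmatched IDs held 0.0458% to 0.0651% of counts per library. The release behind the deposited table may differ, and its positions are those of release 29. Names were taken from a table that pairs IDs with symbols, and 20 list genes were found under an older name in the deposited table. Total counts were 39454210 to 45828807 per library. A count of 0 in a single library allows a level of up to 0.0662 to 0.0742 CPM (3 counts). Intervals and floors cover counting error only, since reads of 1 amplified molecule are not independent.

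The design was fixed before the data were examined. The labels give 1 group, so no test between groups was made. Expected counts were rounded to whole numbers for all count tests. CPM values used effective library sizes from edgeR 4.0.16 (TMM), with factors of 1.02, 0.963, 0.988 and 1.03. A gene was called detected at 1 CPM or more in all 4 libraries. Variation between libraries was tested per gene with a chi-square test of homogeneity (3 degrees of freedom) against expectations in proportion to the effective library sizes, for genes with a mean of 10 or more counts, with Benjamini-Hochberg adjustment at 0.05. The biological coefficient of variation is the square root of edgeR's common dispersion with an intercept-only design. HDAC8 was compared with HDAC1, HDAC2 and HDAC3 by the log2 ratio within a library and an exact sign-flip permutation test. Logs of single genes used a pseudocount of 0.01 CPM, and the HDAC ratios none.

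The 26 gene lists covered zinc-dependent deacetylases, sirtuins, lysine acetyltransferases, deacetylase corepressors, cohesin, reported KDAC8 substrates, mesenchymal and matrix genes, pericellular proteolysis, RAS-MAPK output, G1/S and G2/M genes, replication-dependent histones, p53 targets, interferon-stimulated genes, hypoxia and glycolysis, stress responses, cholesterol synthesis, immediate early and heat shock genes, mitochondrially encoded mRNAs, ribosomal proteins, structural noncoding RNAs, and markers of epithelial, haematopoietic, endothelial, muscle and neural cells. They held 354 genes, of which 349 were matched to a row by symbol or table name and 5 were not (H3C2, RNU2-2, RNA18SN5, RNA28SN5 and RNA45SN5). A row under HIST1H3B, the older name of H3C2, stood at 238 ± 24.7 CPM. The match missed it, so the histone list values leave it out. For each list the mean over members at 1 CPM or more of the deviation from the gene's mean log2 CPM was taken per library. Its SD over libraries was ranked among 10000 random lists of the same size, matched on mean expression in 20 bins, with Benjamini-Hochberg adjustment over the lists. Genes are not independent replicates, so these p-values describe these libraries. The genes named were the HDAC, SIRT and cohesin genes, the 10 with the highest mean CPM, the 10 with the largest SD of log2 CPM among varying genes at a mean of 10 CPM or more, and in each other list the 4 highest members and the most variable member at 1 CPM or more. In lists of other cell types, members at 1 CPM or more were named, or otherwise the highest. Genes named outside this rule are marked as such, and some genes that the rule names are not reported here.

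The methods were tested on simulated data. With counts drawn for the real genes and 1 library changed for 50 genes per fold size, the chi-square test on 16790 genes called 60% at 1.2-fold, 60% at 1.5-fold, 88% at 2-fold and 94% at 4-fold, and 8 of 16590 unchanged genes. A simulated coefficient of variation of 0.0894 over 15366 genes was recovered as 0.0898. Of 40 simulated lists of 15 genes, 4 with no shift passed an unadjusted p of 0.05, against 5 with a shift of 0.05, 16 with a shift of 0.1 and 40 with a shift of 0.2 log2 units in 1 library. The 4 of 40 with no shift are more than a p of 0.05 should let pass, on few lists. Apart from the shift, the simulated genes varied independently, so unshifted lists whose members move together were not simulated.

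Alternatives were DESeq2 1.42.0 size factors, total counts alone, a total without mitochondrial and structural RNA genes, exonic length, a pseudocount of 1 CPM on the HDAC ratios, other detection limits and count filters, edgeR's tagwise and DESeq2's gene dispersions, other list settings, and leaving out each replicate. Scripts ran in Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9) and R 4.3.3.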

Results

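HT1080 is a human fibrosarcoma cell line that carries an activated NRAS allele. RNA was sequenced from HT1080 cells in which KDAC8 was knocked out. KDAC8 is the lysine deacetylase encoded by HDAC8, an enzyme that removes acetyl groups from the cohesin subunit SMC3. The series holds 1 group of 4 replicate libraries, made from total RNA after removal of ribosomal RNA, and no parental or control library was analysed here. The aim stated in the series title is the effect of the knockout on gene expression, and that comparison cannot be made within 1 group. The values reported are therefore levels in the knockout libraries, comparisons between genes within a library, and the spread between the libraries. Total counts were 39454210, 43722295, 45828807 and 41241908 in replicates 1 to 4. The labels do not say whether the replicates were separate cultures, so tests across libraries measure only the spread between these samples, which may be technical. Levels are given as CPM, the count scaled to a common effective library size, and errors are SD over the 4 libraries (n = 4) unless stated otherwise. CPM is not divided by gene length, so genes called highest or lowest are ranked by counts, and the order can differ per kilobase of exon. Exonic length joins all annotated exons of a gene, so values per kilobase depend on the annotation, whichever transcripts the cells make.

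HDAC8 transcripts were scarce but present in every knockout library. HDAC8 (ENSG00000147099, chromosome X, 72329516 to 72573199, GRCh38, reverse strand, protein-coding) had 80, 89, 95 and 107 counts in replicates 1 to 4. These gave 1.98, 2.11, 2.10 and 2.53 CPM, a mean of 2.18 ± 0.242 CPM (SD, n = 4). The exact Poisson 95% interval was 63.4 to 99.6 counts for the lowest library and 87.7 to 129 counts for the highest. Of the genes detected in all 4 libraries, 6.78% had a lower mean than HDAC8. No difference between the 4 libraries beyond counting noise was detectable for HDAC8 at this depth (chi-square test of homogeneity, adjusted p = 0.404). A count over the whole gene does not show whether the targeted exons were read, and a transcript that carries a small deletion would still be counted. The level therefore does not check the knockout label by itself.

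HDAC8 lay far below HDAC1, HDAC2 and HDAC3, the other class I deacetylases, in each library. HDAC1 stood at 103 ± 8.84 CPM, HDAC2 at 182 ± 12.9 CPM and HDAC3 at 37.5 ± 2.75 CPM. The log2 ratio of HDAC8 was -5.57 ± 0.25 to HDAC1, -6.38 ± 0.24 to HDAC2 and -4.11 ± 0.22 to HDAC3, which is 47.5-fold, 83.5-fold and 17.2-fold lower. HDAC8 was the lower gene in 4 of 4 libraries in each comparison. The exact two-sided sign-flip permutation p was 0.125 for each of the 3 comparisons, before and after Benjamini-Hochberg adjustment. It is the smallest that 4 libraries allow, so the test cannot reach 0.05. Per kilobase of exon the log2 ratios were -8.10, -6.96 and -6.42. The annotated exonic length was 22986 bases for HDAC8, against 3963, 15461 and 4631 for HDAC1, HDAC2 and HDAC3. The wider gap per kilobase follows from these lengths and need not hold for the transcripts made.

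All 11 zinc-dependent deacetylase genes were detected at 1 CPM or more in all 4 libraries. After HDAC2 and HDAC1 came the class IIa members HDAC7 at 81.4 ± 4.42 CPM, HDAC9 at 55.1 ± 2.23 CPM and HDAC5 at 39.4 ± 2.28 CPM. HDAC10 (18.0 ± 1.54), HDAC4 (17.7 ± 0.314) and HDAC6 (15.5 ± 1.35), the tubulin deacetylase, formed a lower tier. HDAC11 was nearest to HDAC8 in CPM, at 2.43 ± 0.263. Per kilobase of exon HDAC11 stood at 0.460 CPM and HDAC8 at 0.0948 CPM, and HDAC1 (26.1) exceeded HDAC2 (11.7). The gap between HDAC11 and HDAC8 there rests on annotated exonic lengths of 5281 and 22986 bases. Of the 11 genes, all but HDAC4, HDAC8 and HDAC11 varied between libraries beyond counting noise, 8 over all genes and 8 when adjusted over the list alone. None differed by 1.5 times between its highest and lowest library.

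**Figure D1:**
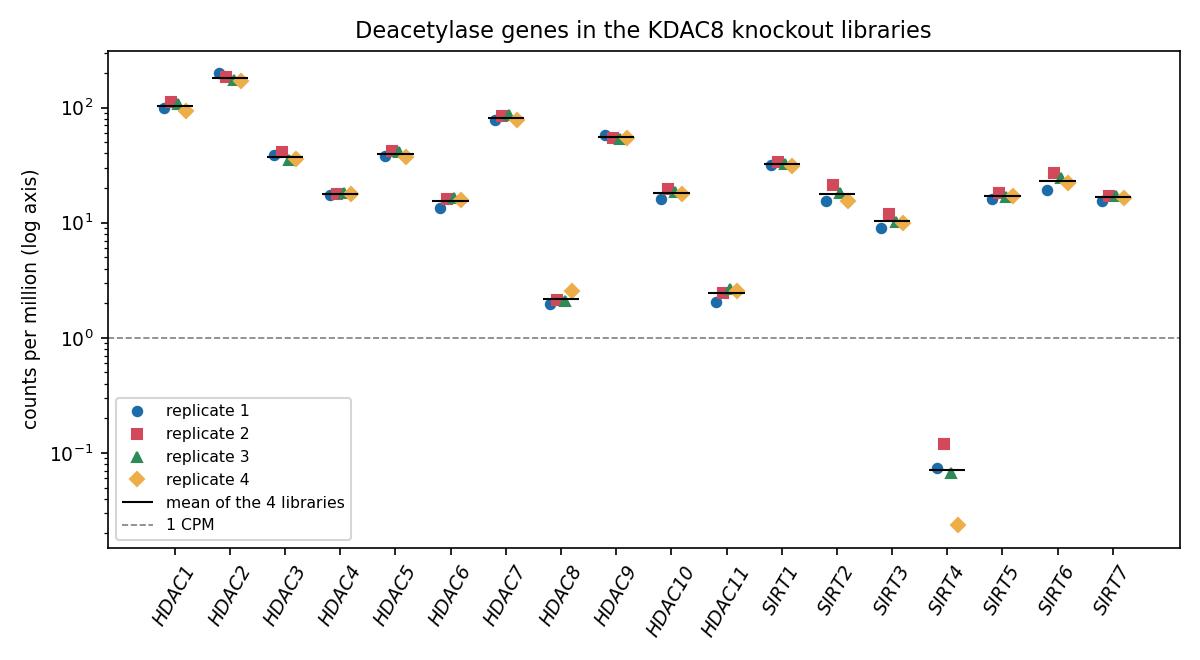
Level of each zinc-dependent deacetylase (HDAC) and sirtuin (SIRT) gene in the 4 KDAC8 knockout libraries, in CPM on a log axis; symbols are libraries, black bars are means over the 4 libraries and the dashed line marks 1 CPM. HDAC8 and HDAC11 lie near 2.18 and 2.43 CPM, HDAC2 at 182 CPM, and SIRT4 lies below 1 CPM.

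The NAD-dependent sirtuins and the acetyltransferases that oppose them were expressed at moderate levels. SIRT1, a nuclear deacetylase, was the highest sirtuin in CPM, at 32.3 ± 1.12, while per kilobase of exon SIRT6 (8.31) exceeded SIRT1 (7.11). SIRT6 (23.2 ± 3.29), SIRT2 (17.6 ± 2.83), SIRT5 (17.0 ± 0.868), SIRT7 (16.6 ± 0.804) and the mitochondrial SIRT3 (10.3 ± 1.23) followed. SIRT4 was at 0.0707 ± 0.039 CPM, so 6 of the 7 sirtuins were detected. Of the 6 tested, 3 varied (SIRT2, SIRT3 and SIRT6), and 3 did when adjusted over the list alone. All 11 lysine acetyltransferases were detected, led by KAT6A (113 ± 7.44), EP300 (108 ± 9.26), CREBBP (97.8 ± 8.83) and KAT7 (76.6 ± 3.04). The tubulin acetyltransferase ATAT1 was the lowest of that list and its most variable member, at 4.79 ± 0.601 CPM. In this list 9 genes varied, and 10 when adjusted over the list alone. The 20 corepressor genes that work with deacetylases were all detected, with a median of 111 CPM. Among their highest members were the NuRD helicase CHD4 (442 ± 19.1), TBL1XR1 (360.4 ± 26.1, the most variable) and NCOR1 (153 ± 8.07). Of these 20 genes, 17 varied, and 17 did when adjusted over the list alone.

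Cohesin, whose SMC3 subunit is the best-known KDAC8 substrate, was expressed in full. All 16 genes of the cohesin list were detected, with a median of 92.8 CPM. The kleisin RAD21 was highest at 362 ± 19.4 CPM, followed by STAG2 (238 ± 12.5), PDS5A (236 ± 14.5), SMC1A (135 ± 17.5) and SMC3 (130.4 ± 6.04). STAG1 stood at 120.0 ± 2.12 CPM, so STAG2 exceeded its paralog in every library. The loader subunits NIPBL and MAU2 had 114 ± 6.91 and 48.0 ± 0.853 CPM. The release factor WAPL had 109 ± 4.31 CPM and PDS5B 77.0 ± 5.06 CPM. ESCO1 and ESCO2, the acetyltransferases that modify SMC3, were close to each other at 26.7 ± 1.61 and 25.9 ± 1.73 CPM. Sororin (CDCA5) had 44.9 ± 2.55 CPM, shugoshin (SGO1) 22.7 ± 0.678, separase (ESPL1) 39.5 ± 1.63 and securin (PTTG1) 62.1 ± 4.41 CPM. SMC1A had the widest range of the list, 1.37 times between its lowest library, replicate 2, and its highest, replicate 4. In this list 12 genes varied, and 13 when adjusted over the list alone. The 9 genes whose proteins have been reported as KDAC8 substrates, a list that includes SMC3, were all detected, with a median of 135 CPM. THRAP3 (249.9 ± 10.9), CTTN (228 ± 15.9) and ZRANB2 (143 ± 7.32) were among the highest and ARID1A (135 ± 13.8) was most variable. All 9 varied, over all genes and when adjusted over the list alone.

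In all, 12984 genes reached 1 CPM in all 4 libraries, and 11570 of them (89.1%) were protein-coding. The highest levels in CPM were those of short structural RNAs. RN7SL1 and RN7SL2, the RNA of the signal recognition particle, had 29115 ± 6417 and 19682 ± 3958 CPM. RN7SK, which holds back transcription elongation, had 24059 ± 4059.9 CPM, and RPPH1, the RNA of ribonuclease P, 9279.7 ± 2715 CPM. The mRNAs with the most counts were EEF1A1 (13018 ± 1006), the mitochondrial MT-CO1 (8068 ± 989.9), ACTB (4713 ± 197), VIM (4701 ± 283), GAPDH (4297 ± 313) and EEF2 (3904 ± 438). Per kilobase of exon MT-CO1 (5232) exceeded EEF1A1 (2189), as did MT-CO3 (4043), MT-CO2 (3679) and MT-ND4 (2448). RN7SL1, RPPH1 and RMRP each have a second row in the table over overlapping bases, so the split of reads between the paired rows is uncertain.

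Of the 25 mesenchymal and matrix genes, 19 were detected. The intermediate filament gene VIM was highest, followed by COL6A3 (3624 ± 248), the hyaluronan receptor CD44 (1560.1 ± 85.8) and fibronectin, FN1 (633 ± 118). Other collagens of the list, picked after their values were seen, ranged widely. COL4A2 and COL4A1 of the basement membrane had 329 ± 27.5 and 192 ± 18.1 CPM, and COL6A2 and COL6A1 had 143 ± 10.7 and 110.4 ± 7.62 CPM. Some fibrillar collagens were low, with COL1A1 at 2.17 ± 0.219 CPM, COL1A2 at 0.0769 ± 0.0454 and COL3A1 at 0.0121 ± 0.014. COL5A1 stood higher, at 24.5 ± 3.82 CPM. COL5A2 was the most variable member, at 1.13 ± 0.243 CPM, with no variation beyond counting noise (chi-square test, adjusted p = 0.134). Of 21 members tested, 17 varied, and 18 did when adjusted over the list alone. In the pericellular proteolysis list, 10 of 11 genes were detected. The membrane protease MMP14 (795 ± 73.5), TIMP2 (344 ± 26.7) and the urokinase gene PLAU (301 ± 18.9) were among its highest members. MMP9 was near the detection limit at 1.14 ± 0.229 CPM. Here 9 of 11 genes varied, and 9 when adjusted over the list alone.

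Genes downstream of RAS and MAPK signalling were expressed in 11 of 12 cases. PHLDA1 (929 ± 15.1), CCND1 (754 ± 10.9), FOSL1 (355 ± 28.3) and the phosphatase DUSP4 (235 ± 2.94) were highest, and ETV4 (52.5 ± 5.19) most variable. The exception was DUSP6, the cytoplasmic ERK phosphatase, at 0.359 ± 0.146 CPM. Of the 12 genes, 8 varied, and 8 when adjusted over the list alone.

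All 20 G1/S genes and all 22 G2/M genes were detected. The G1/S list was led by MCM7 (273 ± 21.1), MCM4 (200.1 ± 6.78), MCM2 (198 ± 14.1) and RRM1 (146 ± 3.49), with CLSPN (52.3 ± 5.86) most variable. The G2/M list was led by TOP2A (507 ± 18.0), CENPF (398 ± 21.7), MKI67 (371 ± 55.9, the most variable) and TPX2 (261 ± 4.90). Varying members numbered 15 of 20 in the G1/S list and 21 of 22 in the G2/M list, against 17 and 21 when adjusted over the list alone. Replication-dependent histones were detected for 14 of the 17 genes matched to a row, which leave out H3C2. They were led by H4C14 (485 ± 97.7), H1-4 (455 ± 32.1), H1-2 (438 ± 54.4) and H4C3 (358 ± 33.5). H4C8 was the most variable at 221 ± 50.4 CPM. H4C14 has a near-identical copy, so its count is uncertain. H1-3 and H3C7 had 0 counts in all 4 libraries, which allows up to 0.0176 CPM over the 4 libraries, and H1-5 had 1 count in replicate 3 only. RNU4-2, the U4 RNA that every cell uses to splice, named after its values were seen, was also at 0 counts in all 4 libraries. A 0 in this table therefore does not by itself show that a gene is not transcribed, and the limit covers counting error only. All 14 tested histone genes varied, over all genes and adjusted over the list alone.

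**Figure D2:**
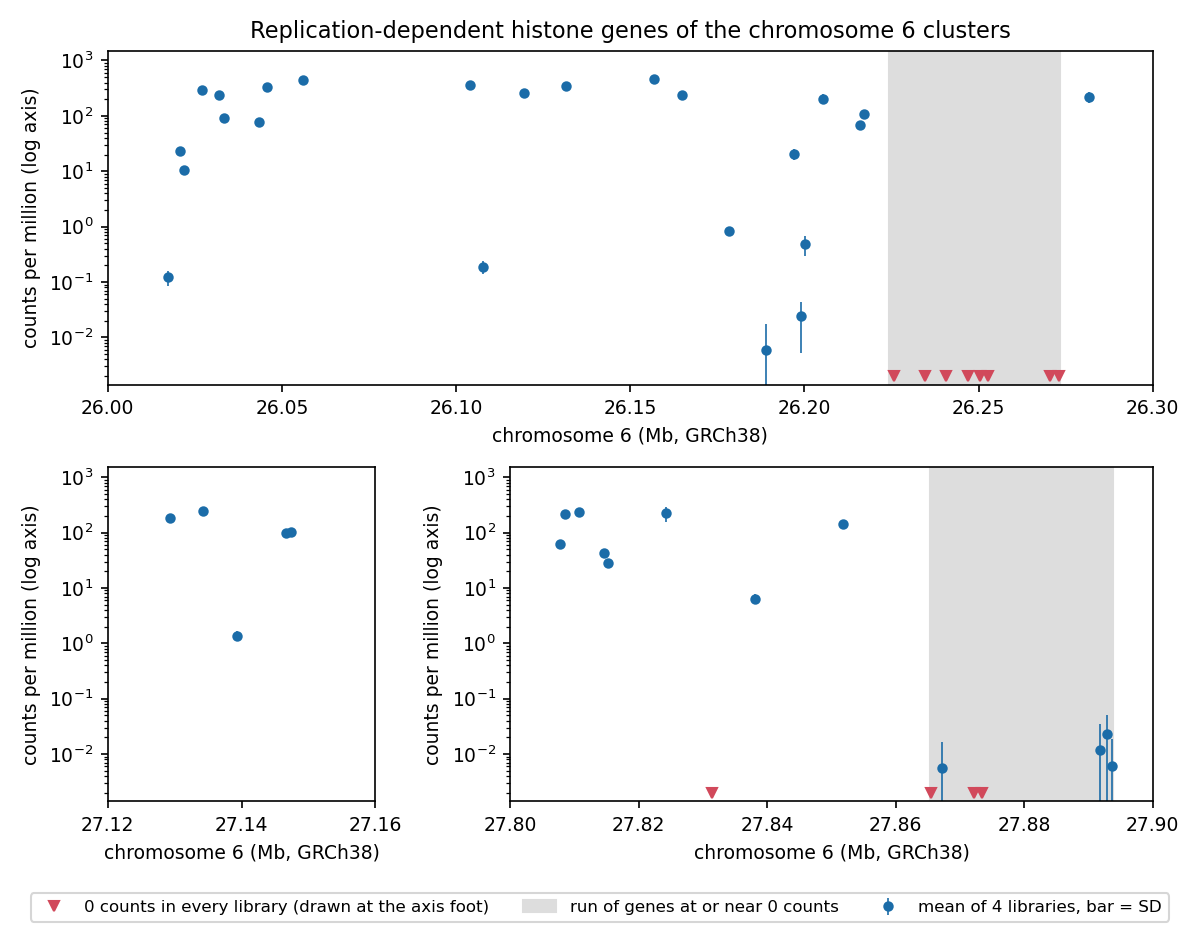
Mean level of each histone gene in CPM (log axis) against position on chromosome 6 (Mb, GRCh38), with SD over the 4 libraries as bars; the pair of genes near 25.7 Mb, both at 0, is not drawn. The grey bands mark 8 consecutive genes at 0 counts and 7 consecutive genes with 8 counts in total, beside genes such as H4C8 at 221 CPM.

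Stress and signalling programmes differed in level. All 15 p53 targets were detected, led by TNFRSF10B (306 ± 17.6), MDM2 (238 ± 8.14), GDF15 (193 ± 11.3) and ZMAT3 (184 ± 8.14). PHLDA3 was the most variable at 49.6 ± 8.41 CPM, and 12 of the 15 varied, or 13 when adjusted over the list alone. All 13 genes of the integrated stress and unfolded protein responses were detected and varied, also when adjusted over the list alone. HSPA5 (565 ± 52.3), ATF4 (557 ± 50.4), PSAT1 (555 ± 26.7) and ASNS (368 ± 19.1) were highest and CHAC1 (26.4 ± 4.04) most variable. Interferon-stimulated genes were low, with 13 of 18 detected and a median of 2.47 CPM. OAS3 (15.5 ± 0.922), RIGI (9.16 ± 0.752) and IRF9 (7.02 ± 1.19, the most variable) were among the highest. Of 15 tested, 2 varied, IRF9 among them, and 2 did when adjusted over the list alone. Per kilobase of exon, 6 of the 18 reached 1 CPM.

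In the hypoxia and glycolysis list 12 of 14 genes were detected. The glycolytic genes ENO1 (2399 ± 146), LDHA (1064 ± 38.4), ALDOA (1011 ± 63.5) and PGK1 (498 ± 16.3) led it. The hypoxia marker CA9 stood at 3.97 ± 0.912 CPM and was the most variable member, with its lowest value, 2.61 CPM, in replicate 2. Of 12 tested, 11 varied, and 11 when adjusted over the list alone. Of the cholesterol synthesis genes, 13 of 14 were detected and 13 varied, also when adjusted over the list alone. SREBF2 (208 ± 11.2), FDFT1 (79.7 ± 7.67) and FDPS (77.4 ± 6.10) were among the highest. Among immediate early and heat shock genes, 11 of 12 were detected. JUN (206 ± 13.1), IER2 (115 ± 9.40), DNAJB1 (92.4 ± 3.32) and IER3 (84.8 ± 6.53) led, while FOS was at 1.55 ± 0.317 CPM. In that list 7 of 12 varied, and 7 when adjusted over the list alone.

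Markers of other cell types were mostly below the detection threshold. Of 42 such markers, 7 were detected and 14 had 0 counts in every library. The simple-epithelium keratins KRT8 (229.7 ± 21.5) and KRT18 (159 ± 11.7) were the highest, and CLDN4 had 2.49 ± 0.438 CPM. The epithelial genes EPCAM, CDH1 and KRT5, named after their values were seen, had 0 counts in all 4 libraries, under the same limit of 0.0176 CPM. In the neural list TUBB3 had 127 ± 15.7 CPM, NEFL 6.61 ± 0.612 and MAP2 2.80 ± 0.303 CPM. No haematopoietic or endothelial marker was detected, the highest being LYZ at 0.525 ± 0.257 and TEK at 0.654 ± 0.11 CPM. The only muscle marker detected was embryonic myosin, MYH3, at 2.46 ± 0.293 CPM. All 3 detected epithelial markers varied, as did 1 of 4 tested neural markers (TUBB3) and the 1 haematopoietic marker tested (LYZ). Of the 2 endothelial markers and the 1 muscle marker tested, 0 varied, and the counts adjusted over each list alone were the same for these 5 lists.

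Replicate libraries were close but differed by more than counting. Of 16790 genes with a mean of 10 or more counts, 9944 (59.2%) varied beyond counting noise (chi-square test, Benjamini-Hochberg adjusted p under 0.05). Over all genes tested, 2021 varied with a range of 1.5 times or more between the highest and lowest library and 1251 with a range of 2 times or more. Most of these had a low level: of 9480 genes with a mean of 10 CPM or more, 166 varied with a range of 1.5 times or more and 45 with a range of 2 times or more, 14 of which were protein-coding. The median SD of log2 CPM in these genes was 0.09. The biological coefficient of variation, the spread that remains after counting noise, was 0.0894. All pairs of libraries differed by more than sampling noise. The closest pair by the number of differing genes, replicates 2 and 3, differed in 4158 genes, and the most distant, replicates 2 and 4, in 7668 genes.

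The most variable genes were short structural RNAs, mitochondrial sequences and noncoding RNAs. The second RPPH1 row ranged 7.04 times, from 104.5 CPM in replicate 1 to 736 CPM in replicate 2. The second RMRP row (3.57 times) and the small nucleolar RNA SNORA73A (2.52 times) were also lowest in replicate 1 and highest in replicate 2. The mitochondrial pseudogene MTATP6P1 (4.06 times) and the mitochondrial mRNA MT-ND4L (2.71 times) were lowest in replicate 2 and highest in replicate 4. HMGA2-AS1, an RNA antisense to the chromatin gene HMGA2, had 13.4, 13.8, 13.2 and 36.5 CPM, while HMGA2 itself, named after its values were seen, had 404 ± 21.4 CPM. The second RN7SL1 row ranged 2.69 times, from 23.7 CPM in replicate 1 to 63.6 CPM in replicate 4. On chromosome 21, 3 noncoding rows, CH507-513H4.3, CH507-513H4.4 and CH507-513H4.6, ranged 2.56 times. Those 3 rows hold identical values, so reads were shared among copies and their counts are uncertain, as are those of MTATP6P1 and of HMGA2-AS1, since strand use is not stated.

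Composition moved in the same way. RN7SL1, RN7SL2, RN7SK, RPPH1 and RMRP together took 6.94%, 10.5%, 8.99% and 7.98% of counts in replicates 1 to 4. Mitochondrially encoded RNAs took 1.99% in replicate 2 and 3.28% in replicate 4, and long noncoding RNAs 1.15% and 1.57%. The Wilson 95% intervals of these shares were within 0.00907 percentage points of the value and cover counting error only.

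The gene lists that moved most between libraries were tested against 10000 random lists of the same size and expression. Of 23 lists with at least 3 members at 1 CPM, 5 had a larger spread than matched lists at an adjusted p under 0.05. The 13 mitochondrially encoded mRNAs, among them MT-ND4 (3373 ± 661), MT-CO3 (3169.8 ± 463) and MT-CO2 (2516 ± 449.9), had a mean log2 shift of -0.44 in replicate 2 and 0.35 in replicate 4 (adjusted p = 0.00115). The structural noncoding RNAs, of which 9 of 10 matched to a row were detected (all but RNU4-2), ran from -0.28 in replicate 1 to 0.41 in replicate 4 (adjusted p = 0.00115). Its members went different ways: NEAT1, MALAT1, MT-RNR1 and MT-RNR2, the first 2 and the last named after their values were seen, were highest in replicate 4, while RN7SL1, RN7SL2, RN7SK and RPPH1 were highest in replicate 2. The mitochondrial ribosomal RNAs MT-RNR1 (4.57 ± 3.79 CPM, the most variable) and MT-RNR2 (9.13 ± 7.67 CPM) were low. Their SD of log2 CPM was 1.16 and 1.12, against 0.59 for NEAT1. Members weigh equally in the list mean, so these 2 weigh heavily in its shift. Both are ribosomal RNAs, and ribosomal RNA was removed before sequencing. Before adjustment the mitochondrial mRNA list and the structural list each had a p of 1e-04, the smallest that the random lists can give. All 13 mitochondrial and all 9 tested structural genes varied, also adjusted over the list alone. Ribosomal protein mRNAs, led by RPS2 (2614 ± 459, the most variable), RPLP0 (2396 ± 278), RPL3 (2369 ± 259.8) and RPL4 (2094 ± 171), were highest in replicate 2 (0.18) and lowest in replicate 4 (-0.14), with an adjusted p of 0.0069, and 18 of 18 varied, also adjusted over the list alone. With a trend on GC content and gene length subtracted, an alternative added after seeing the data, their spread fell from 0.14 to 0.08 log2 units (adjusted p = 0.0236). Under that alternative the structural list was lowest in replicate 2 (-0.34), with replicate 1 at -0.18 and replicate 4 at 0.51. Histones were highest in replicate 2, at 0.22 (adjusted p = 0.0023). With the same trend subtracted, the histone spread fell from 0.16 to 0.03 log2 units and the adjusted p was 0.465. The p53 targets passed narrowly, with 0.10 in replicate 2 and -0.10 in replicate 4 (adjusted p = 0.0488), and did not pass under DESeq2 size factors (0.052), under library totals alone (0.394), without replicate 4 (0.0826) or with the GC and length trend subtracted, where the spread fell from 0.09 to 0.03 (0.410). The cohesin, deacetylase and KDAC8 substrate lists had adjusted p of 0.573, 0.486 and 0.885, and the 18 lists that did not pass ranged from 0.0538 to 0.885. Sirtuins, at 0.0538, passed without replicate 3 (0.036) and without replicate 4 (0.0328). The stress response list, also at 0.0538, passed without replicate 2 (0.0023), and the immediate early and heat shock list without replicate 2 (0.0457) and without replicate 4 (0.0368). Cholesterol synthesis, at 0.105, passed with library totals alone (0.0193) and with the GC and length trend subtracted (0.0184).

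**Figure D3:**
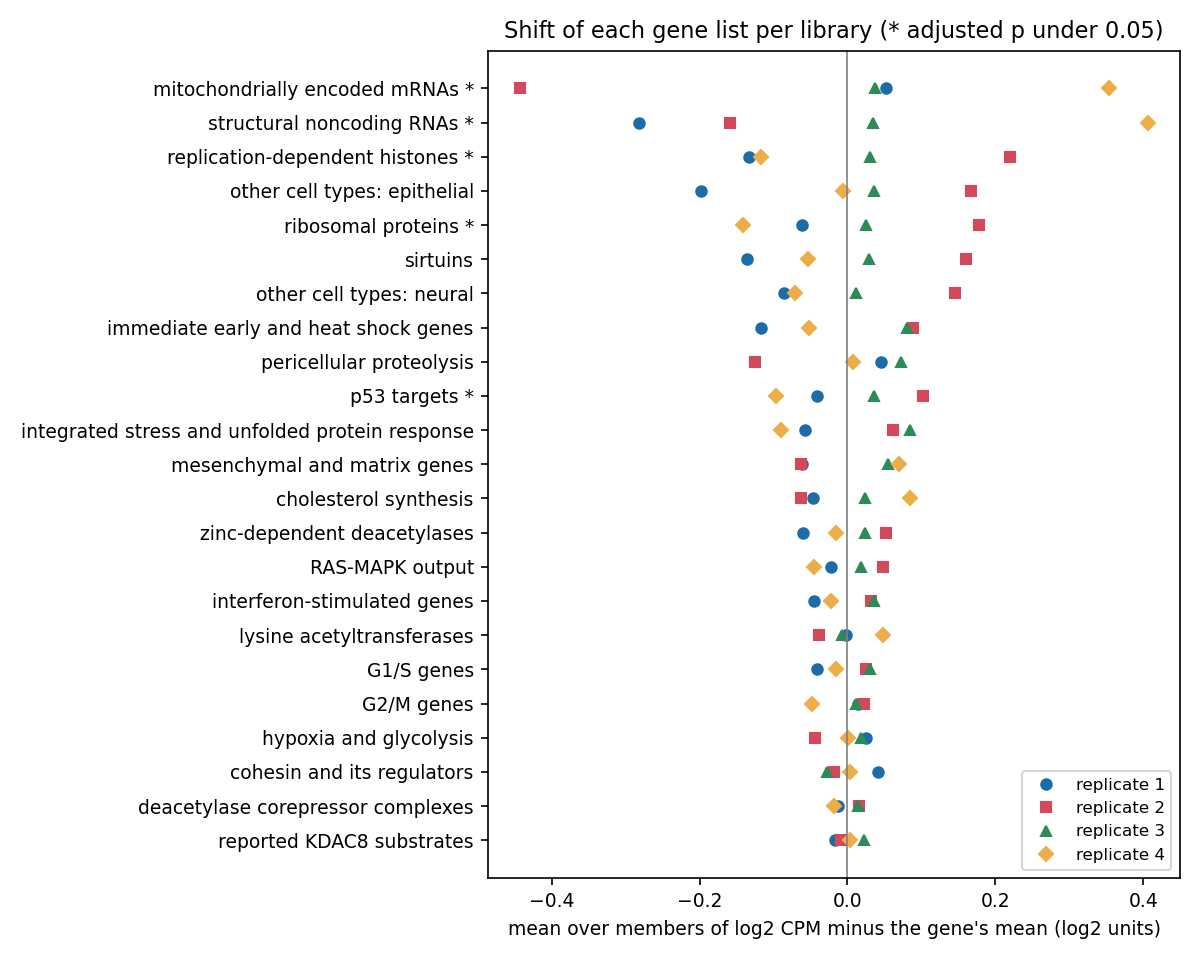
Mean over list members of log2 CPM minus the gene's mean (log2 units, x axis) in each of the 4 libraries for the 23 lists with at least 3 members at 1 CPM, ordered by spread; an asterisk marks an adjusted p under 0.05. Mitochondrially encoded mRNAs span -0.44 to 0.35, and the cohesin and KDAC8 substrate lists stay close to 0.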

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

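The tests on scaling factors, GC content alone, recovery of short RNAs and a larger share of nuclear RNA were chosen only after the result was seen, and those on GC content with length and on genomic DNA after the pattern but before their own result. Of 167 reported values looked at across the 4 libraries, 7 had 1 library far from the others by Dixon's ratio (the gap divided by the range), where chance gives about 1 in 20, or 8.35. No design-given biological explanation exists for differences between replicates of 1 group, so none was tested.

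HMGA2-AS1 had the most extreme library, with 36.5 CPM in replicate 4 against 13.2 to 13.8 CPM in the others (ratio 0.977). PSAT1 was lowest in replicate 4, at 515 CPM against 567 to 571 (ratio 0.93). The G2/M list was also lowest there, with a mean log2 shift of -0.05 (ratio 0.842). Its spread over the libraries did not exceed that of matched random lists (adjusted p = 0.486). Replicate 2 was lowest for CD44, at 1432 CPM against 1592 to 1612 (ratio 0.889) and for CA9, at 2.61 CPM against 4.26 to 4.52 (ratio 0.862). In replicate 1, PDS5A was highest, at 258 CPM against 227 to 232 (ratio 0.863), and DUSP4 lowest, at 230.2 CPM against 236 in the others (ratio 0.899). For DUSP4 the highest library was only 1.03 times the lowest, and no difference beyond counting noise was detectable (chi-square test of homogeneity over all genes, adjusted p = 0.266).

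Short structural RNAs took a larger share in replicate 2. RN7SL1, RN7SL2, RN7SK, RPPH1 and RMRP, without their second rows, held 10.4% of raw counts there and 7.93% on average in the other libraries, a ratio of 1.31 that no scaling factor enters. The other libraries were not alike: with second rows included, the shares were 6.94%, 8.99% and 7.98% in replicates 1, 3 and 4. The main RMRP row had more counts in replicate 3 (184831) than in replicate 2 (168789). The median log2 difference of the 5 RNAs in replicate 2 from the other libraries was 0.41 (SD over the RNAs 0.19). It was 0.32 (SD 0.18, lowest RNA 0.06) after the GC trend of nuclear protein-coding genes was subtracted, which argues against GC content as the whole source. Better recovery of short RNAs stays open as a candidate explanation, since the other 36 genes with under 500 bases of exon had a median of 0.20, above all 10000 random lists, and 26 of them lay above 0. More of these were histone genes (19, median 0.19), which the report already gives as highest in replicate 2, or copies of RN7SL (2) than were not, and the 15 others, with 8 small nuclear and nucleolar RNAs among them, had a median of 0.21, with 10 above 0 (95th percentile of matched random lists 0.08).

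Among 162 long noncoding RNAs with a mean of 10 CPM or more, 25 (15.4%) in replicate 4 were 1.5 times the mean of the other libraries or more, against 24 of 9196 protein-coding genes (0.261%, Fisher's exact p = 5.98e-32, two-sided, across genes, which are not independent). That comparison was not part of the fixed design, was made on a pattern seen in these libraries and was not matched on expression. Of the 162 RNAs, 79 were higher in replicate 4 than in each other library. NEAT1, the scaffold of paraspeckles, had 596 CPM there and 255 to 271 CPM in the others, and HELLPAR 477 against 222 to 262 CPM, both named after their values were seen. A trend on GC content and length did not account for it: the median over the 162 RNAs was 0.07 before and 0.13 after its subtraction, above the highest of 10000 random protein-coding lists (0.05). The exons of 380 olfactory receptor genes argue against carry-over of genomic DNA as the whole source. Their excess in replicate 4 was 0.00696 CPM per kilobase (95% counting interval 0.00555 to 0.00838), where the median long noncoding RNA gained 0.214. These exons did rise, to 0.0166 CPM per kilobase in replicate 4 against 0.00825 to 0.0106 in the others. The mitochondrially encoded mRNAs were higher in replicate 4 in 13 of 13 cases (median 0.43, SD 0.15), so nuclear RNA was not the only class to rise. A larger share of nuclear RNA is not excluded, since mitochondrial RNA could rise along with it. What sets replicate 4 apart stays open, and the labels give no batch.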

How the results depend on the processing

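Of the alternatives, the subtraction of a trend on GC content and length was chosen after seeing the data. Of 68 values of the main results under the alternatives, 4 moved and 64 did not. For the HDAC8 ratios, not moved means only the same direction, since the permutation test was not rerun. For counts of genes or lists it means within 1.5 times the main value. For the HDAC8 level and the coefficient of variation it means under 1 SD away. Values counted as not moved can therefore differ: 10542 genes were detected at 5 CPM in all 4 libraries, against 12984. With the GC and length trend subtracted 4 lists passed, 3 of them among the main 5. Per kilobase of exon HDAC8 was 275-fold lower than HDAC1, 124-fold lower than HDAC2 and 85.6-fold lower than HDAC3, against 47.5-fold, 83.5-fold and 17.2-fold. This divides each gene by the joined length of its annotated exons, 22986 bases for HDAC8, so the wider gaps come from the annotated lengths. HDAC8 was at 2.46 CPM when mitochondrial and structural RNA genes were left out of the total, which raises every other gene by construction. The varying genes numbered 5859 of 15544 when called by an edgeR tagwise dispersion above 0.01, against 9944 of 16790. That call limits the size of the spread, where the main test asks only whether it exceeds counting noise, and it covers another set of genes. With the main test, 34.8% of tested genes varied with no filter on low counts and 71.7% at a mean of 100 or more counts, against 59.2%. Lists with a larger spread numbered 11 with the median over members, against 5; the cause was not tested, and all 5 were among the 11. Leaving out each replicate gave a biological coefficient of variation of 0.079 (without replicate 4) to 0.105 (without replicate 3), with 3 libraries per estimate. It also gave 7786 to 9376 varying genes, 2.05 to 2.23 CPM for HDAC8 and 5 to 7 lists. Under all 9 alternatives the mitochondrial, ribosomal protein and structural lists passed, the histones under 8 and the p53 targets under 5. Of 810 calls of variation for named genes, 765 were the same, 36 were lost and 9 gained, 13 of the losses without replicate 1. Of 952 levels of named genes, 101 moved by 1 SD or more, 100 of them with the reduced total. At this depth HDAC8 rests on 80 to 107 counts a library, so differences within its counting interval were not detectable.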

Other observations

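The test of gene order was chosen only after the result was seen, and those on gene length and shared sequence after the pattern but before their own result. The histone clusters of chromosome 6 held 2 stretches of genes at or near 0 counts. Of 55 annotated histone genes there, 31 were detected and 20 had a mean of 1 count or less, with counts rounded to whole numbers. A run of 8 consecutive genes, H3C6, H1-3, H4C6, H4C7, H3C7, H2BC9, H3C8 and H2BC10 (chromosome 6, 26224199 to 26273356, GRCh38), had 0 counts in all 4 libraries, and so did the other 2 annotated rows between them. The neighbours on both sides, H2AC8 and H4C8, had 106 ± 16.3 and 221 ± 50.4 CPM (SD, n = 4). A second run of 7 genes, H2AC16, H1-5, H3C11, H4C13, H3C12, H2AC17 and H2BC17 (27865355 to 27893843), had 8 counts in total over the 4 libraries, while H2BC15 (142 ± 18.3 CPM), whose annotated end overlaps the start of the run, was expressed. The nearest detected protein-coding genes outside it were low, H2AC15 at 6.45 ± 1.37 CPM on the left and ZSCAN16 at 1.19 ± 0.133 CPM on the right. The linker histone genes H1-3 and H1-5 fell in these runs, while H1-2 and H1-4 stood at 438 and 455 CPM.

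Gene length does not account for these runs, whose median exonic length was 411 bases, within the 312 to 5477 bases of detected histone genes (one-sided permutation p of a shorter median 0.419, 100000 resamples). Reads assigned to near-identical copies do not either, since a median of 100% of the 100-base stretches of these 15 genes occurred in no other annotated gene (lowest 16.0%, in H2AC17). In shuffled gene orders the longest run of genes with a mean of 1 count or less had a median of 3 genes, and 8 or more were found with a permutation p of 0.0039. Loss of both stretches from the genome of these cells and silencing of them may each give such a pattern and were not tested. Genes missed by the library or by the counting stay open too, since the splicing RNA RNU4-2, which every cell uses, also had 0 counts in all 4 libraries. With no parental library analysed here, the runs cannot be tied to the knockout.

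Neighbouring genes at 0 counts were also seen on chromosome 9. CDKN2A (21967753 to 21995301) and CDKN2B (22002903 to 22009363), which encode inhibitors of the cell cycle kinases CDK4 and CDK6, had 0 counts in all 4 libraries, which allows up to 0.0176 CPM. The neighbouring MTAP had 0.486 ± 0.138 CPM and DMRTA1, on the other side, 2.63 ± 0.54 CPM (SD, n = 4). These loci were picked after their values were seen, and no test was made on them. With no parental library analysed here, their counts of 0 cannot be tied to the knockout.

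Across 9480 genes with a mean of 10 CPM or more, 367 (3.87%) had 1 library far from the other 3, below the 1 in 20 that chance gives. Replicate 1 was the highest in 85 of them and replicate 2 the lowest in 79, while replicate 3 stood apart in 19 as the highest and in 13 as the lowest.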
